A study of Mus musculus with 12 samples.

How the data were processed

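Total RNA of sorted mouse CD4+ and CD8+ T cells was measured on 12 single-colour Affymetrix MoGene-2_0-st arrays, 3 in each of 4 groups. Per the labels, whole splenocytes had been kept in culture for 24 h with 50 µM linoleic acid or without it before the T cells were sorted, RNA was prepared with an RNeasy kit, and it was amplified and labelled with the Ambion and Affymetrix whole-transcript kits. The deposited values are log2 intensities, 1 for each of 41345 probe sets on each array. The submitters' processing notes name RMA, which corrects background, normalizes quantiles across arrays and summarizes the probes of a set. The software, its version, the summary level of RMA and the genome build are not given in the sources used here. No probe set had been centred, and the values were taken as deposited with no further normalization.

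Probe sets were named from the platform annotation supplied with the series. Of the 41345 probe sets, 23521 carried a single gene symbol, 1814 carried several and 16010 (38.7%) carried none. An Entrez identifier in the mouse RefSeq gene table was found for 23328 of the 23521, and 0 symbols differed from that table. Probe sets with several symbols were not named. The 22180 named genes included 1082 with more than 1 probe set, and the probe set with the highest mean over the 12 arrays stood for such a gene. Genes whose mean lay below the 40th percentile of all probe set means, log2 4.28, were left out, and 14323 genes were tested. The number of arrays limits the precision of each value.

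Each comparison was a contrast of group means in limma (lmFit and eBayes, two-sided moderated test) on all 12 arrays, with 8 residual and 5.67 prior degrees of freedom, no block, and Benjamini-Hochberg adjustment over the 14323 genes at a threshold of 0.05. The contrasts were linoleic acid against control in CD4 T cells, the same in CD8 T cells, the difference between these effects (CD4 minus CD8), and CD8 against CD4 T cells in control and in linoleic acid culture. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast, and beside it with camera at an estimated correlation and with fry, which tests whether the genes of a list move on balance to one side. There were 29 lists of 594 genes, of which 519 were measured and 482 tested, covering lipid metabolism, mitochondria, stress and cell death, T cell states and lineages, interferon response, glycolysis and other blood cells. A list needed 5 tested members, and 27 had them. The mitochondrial genome list had 0 of its 13 genes among the named probe sets and the erythroid list had 2 tested members, so these were not tested.

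The genes named were fixed by rule. For linoleic acid these were Cpt1a, the 10 largest rises and the 10 largest falls among genes past the threshold whose treated and control arrays did not overlap, and up to 4 members with the smallest p of each list described. Where fewer than 5 genes passed in a direction, the 5 with the largest change among genes with an unadjusted p under 0.05 and non-overlapping arrays were named by their values. For the difference between the effects the 10 largest past the threshold or, with fewer than 5 of these, the 5 genes with the smallest p were named, with Cpt1a. For CD8 against CD4, Cd4, Cd8a, Cd8b1, Zbtb7b and Runx3 were named with the 10 largest differences to each side. The members with the smallest p of each list described were named in these comparisons too, a choice made after the data were seen. Predicted genes, antigen receptor segments, chemosensory receptors and small RNAs were counted but not named. The comparisons, tests, lists, naming rule and alternatives were chosen before the data were examined, except where a choice is said to have come later.

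The labels number the arrays 1 to 3 within each group without saying what a number marks. The deviations of same-numbered arrays from their group means correlated across genes at 0.61, 0.19 and 0.32 for the CD4 groups with and without linoleic acid, at 0.43, 0.19 and 0.42 for the CD8 groups, and at 0.58, 0.26 and 0.52 for CD8 and CD4 in linoleic acid culture. Each of these lies above 0.1, so the numbers were taken to pair the arrays in these comparisons. The pairing comes from the data and not from the labels. Results of the fit with the replicate number as a block are given where they change a call or move a count of calls by more than 1.5 times.

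Chemosensory receptor genes (olfactory and vomeronasal), which T cells are not known to use in quantity, served as a gauge of background, chosen after the data were seen. The array measured 1394 of them. The 95th percentile of their means was log2 5.11, and 4495 of the 14323 tested genes lay below it. Single values and list means were also compared by exact permutation over the 400 relabellings of treated and control arrays within both cell types and, chosen after the data were seen, over the 20 relabellings of whole numbers in both cell types at once, and lists by their place among 10000 random lists matched on mean expression. Counts were repeated for other splits of the same arrays.

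The fit was tested on simulated data with the spread of these arrays, in which 50 of 14323 genes were changed at each of 4 folds between linoleic acid and control in CD4 T cells. Without a block it recovered 32% of genes changed 1.5-fold, 96% at 2-fold, 100% at 4-fold and 100% at 8-fold. With simulated replicate effects and the block it recovered 66%, 94%, 100% and 100%. All 4 folds were simulated in the same comparison, which loosens the Benjamini-Hochberg cutoff, and the noise was drawn independently for each gene. These shares therefore do not give the power of a comparison in which few genes change.

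The alternatives were no filter, a filter at the 60th percentile, the replicate number as a fixed or a random block, arrays centred on their medians, a further quantile normalization, a fit of only the groups compared, an intensity trend with robust moderation, array weights, the mean of a gene's probe sets, all probe sets whether named or not, a minimum of 1.5-fold, an unadjusted threshold, and each array left out in turn. A replicate block within each cell type, the mean receptor gene level of each array as a covariate, array weights estimated gene by gene, and the mean effect over both cell types were added after the data were seen. R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9 were used.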

Results

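The series asks whether CD4 and CD8 T cells, the helper and the cytotoxic arm of T cell immunity, respond differently to linoleic acid, a polyunsaturated fatty acid of the diet. Mouse splenocytes spent 24 h in culture with 50 µM linoleic acid or without it, CD4+ and CD8+ T cells were sorted from them, and the RNA of each sort was hybridized to an array. The 12 arrays form 4 groups of 3, CD4 control, CD4 linoleic acid, CD8 control and CD8 linoleic acid. Values are log2 RMA intensities, with array medians of 4.66 to 4.80 and correlations of 0.946 to 0.984 between arrays. The second principal component, with 26.3% of the variance, parted CD4 arrays (scores up to 16.4, all positive) from CD8 arrays (-19.2 to -12.2). The first, with 33.2%, ran from CD4 control replicate 1 (-23.7) to CD8 linoleic acid replicate 3 (36.1). It followed the replicate number, with scores of -23.7 to -14.8 for number 1, -7.16 to 11.1 for number 2 and 5.42 to 36.1 for number 3. The arrays at its ends had the lowest and the highest mean of the chemosensory receptor genes (2.99 and 3.46). B cell markers, which the sort is meant to remove, had list means of 6.58 to 7.05 in the 4 arrays numbered 1 and of 7.79 to 8.41 in the arrays numbered 2 and 3. The labels do not say that replicates are separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

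Control culture gave the difference between the sorted cell types after 24 h of culture without linoleic acid. CD8 T cells carried 37.5-fold more mRNA of Cd8a (log2 difference 5.23 ± 0.38 SE, n = 3 per group, limma adjusted p = 1.64e-06) and 14.0-fold more of Cd8b1 (3.81 ± 0.19, adjusted p = 7.27e-08), the chains of the CD8 co-receptor. Their Cd4 mRNA, of the CD4 co-receptor, was 29.5-fold lower (-4.88 ± 0.29, adjusted p = 4.09e-07). Runx3, the transcription factor of the CD8 lineage, was 2.16-fold higher (1.11 ± 0.24, adjusted p = 0.0251), and Zbtb7b, which directs the CD4 lineage, was 2.05-fold lower (-1.04 ± 0.20, adjusted p = 0.0116). In limma 280 of 14323 genes passed, 147 higher and 133 lower in CD8 T cells, and 122 of them differed by more than 2-fold. With the replicate number as a block 630 passed, 331 higher and 299 lower. The 3 arrays of each cell type did not overlap for 16.1% of genes, where chance gives 10% for independent arrays. The 280 genes became 176, 179 and 184 without CD8 control replicate 1, CD8 control replicate 2 and CD4 control replicate 3. Runx3 no longer passed without CD8 control replicate 1 (adjusted p = 0.126) or 2 (0.108) or CD4 control replicate 2 (0.0782) or 3 (0.126), nor Zbtb7b without CD4 control replicate 1 (0.0568) or CD8 control replicate 2 (0.0579) or 3 (0.0663).

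Cytotoxic effector genes were higher in CD8 T cells in control culture, with 7 of 22 tested members past the threshold (8 adjusted over the list alone, where 1 more was lower). Nkg7, a granule membrane protein, differed by 2.68, the receptor chain Klrd1 by 2.58, the chemokine Ccl5 by 2.49 and the protease Ctsw by 2.32. Limma's camera gave the list an adjusted p = 1.59e-14, and 0.00389 with an estimated correlation. The CD8 lineage list had 11 of 15 members higher (12 adjusted over the list alone), among them Itgae at 2.70, an integrin chain that binds E-cadherin (camera adjusted p = 3.35e-37, and 0.000315 with an estimated correlation). Of the other genes with the largest differences, the amino acid transporter Slc6a19 stood at 3.12, Bend4 at 2.96 and the endothelial co-receptor Eng at 2.81.

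CD4 T cells held more mRNA of helper and regulatory genes in control culture. The CD4 lineage list had 10 of 14 members lower in CD8 T cells (11 adjusted over the list alone), with Cd40lg, the helper ligand for B cells, at -3.74 and the adaptor Trat1 at -2.04 (camera adjusted p = 8.35e-31, and 0.000315 with an estimated correlation). The regulatory T cell list had 12 of 17 lower and Itgae higher (14 lower and 1 higher adjusted over the list alone), with the regulator Foxp3 at -3.39, the interleukin-2 receptor chain Il2ra at -2.22 and Lrrc32, which anchors latent TGF-beta, at -2.11 (camera adjusted p = 1.23e-31, and 0.000782 with an estimated correlation). The T cell activation list had 7 of 28 lower and 1 higher (8 and 1 adjusted over the list alone), with the costimulatory receptor Tnfrsf4 at -2.03 and the inhibitory receptor Pdcd1 at -1.39. The higher member was Myc at 0.74, chosen after its values were seen. Camera gave the activation list an adjusted p = 1.05e-07, and 0.05 with an estimated correlation, under the threshold before rounding. These 5 lists passed in all 19 alternatives that change a single choice. With the replicate block and an estimated correlation together camera gave the activation list an adjusted p = 0.062, which ends its call. The lists are not independent. Members also in another list were 10 of 15 CD8 lineage, 12 of 22 cytotoxic, 7 of 14 CD4 lineage, 8 of 17 regulatory and 7 of 28 activation genes. The lineage lists hold Cd4, Cd8a and Cd8b1, the genes of the markers sorted for. The sialyltransferase St8sia6 at -3.23, Ecm1 at -2.58 and Tmem64 at -1.98 were also among the largest differences.

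Smaller list differences in control culture did not hold with an estimated correlation in the fit without a block. Of 26 interferon-stimulated genes 21 lay lower in CD8 T cells, with a median of -0.20 and Ifit2 at -0.79 past the threshold, and 8 were lower and 1 higher adjusted over the list alone. Camera gave an adjusted p = 5.3e-06, and adjusted p = 0.282 with an estimated correlation (range over alternatives 3.27e-07 to 0.282). Of 5 platelet markers 1 was lower, the integrin chain Itgb3 at -0.88 (camera adjusted p = 0.015, and adjusted p = 0.0837 with an estimated correlation, range 0.00292 to 0.0837). Of 19 cholesterol synthesis genes 0 passed in limma, 6 had an unadjusted p under 0.05 and 2 were lower adjusted over the list alone. Camera gave this list an adjusted p = 0.0457, and adjusted p = 0.562 with an estimated correlation (range 0.00904 to 0.562). The fatty acid elongase Elovl7 at 1.31, in a gene below the 95th percentile of the receptor genes, and the survival factor Bcl2 at 1.23 also passed. All 15 B cell markers lay lower in CD8 T cells, with a median of -0.32, 0 past the threshold in limma and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0836). With the replicate block 5 of them passed as lower, and camera gave an adjusted p = 1.1e-09, and 0.0342 with an estimated correlation as well. The list means were 7.01, 8.24 and 8.14 in the CD4 control arrays numbered 1, 2 and 3 and 6.58, 7.79 and 7.90 in the CD8 control arrays. This list passed without CD4 control replicate 1 (3.87e-05) or CD8 control replicate 2 (0.00904) or 3 (0.00244), and its direction turned without CD8 control replicate 1 (0.815). The platelet call ended without CD4 control replicate 2 (adjusted p = 0.0686) or CD8 control replicate 3 (0.0799), and the cholesterol call without CD8 control replicate 1 (0.331) or CD4 control replicate 3 (0.251). Itgb3 no longer passed without CD8 control replicate 1 (0.063), nor Ifit2 with any array of the comparison left out except CD4 control replicate 2 (0.0627 to 0.157).

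**Figure D1:**
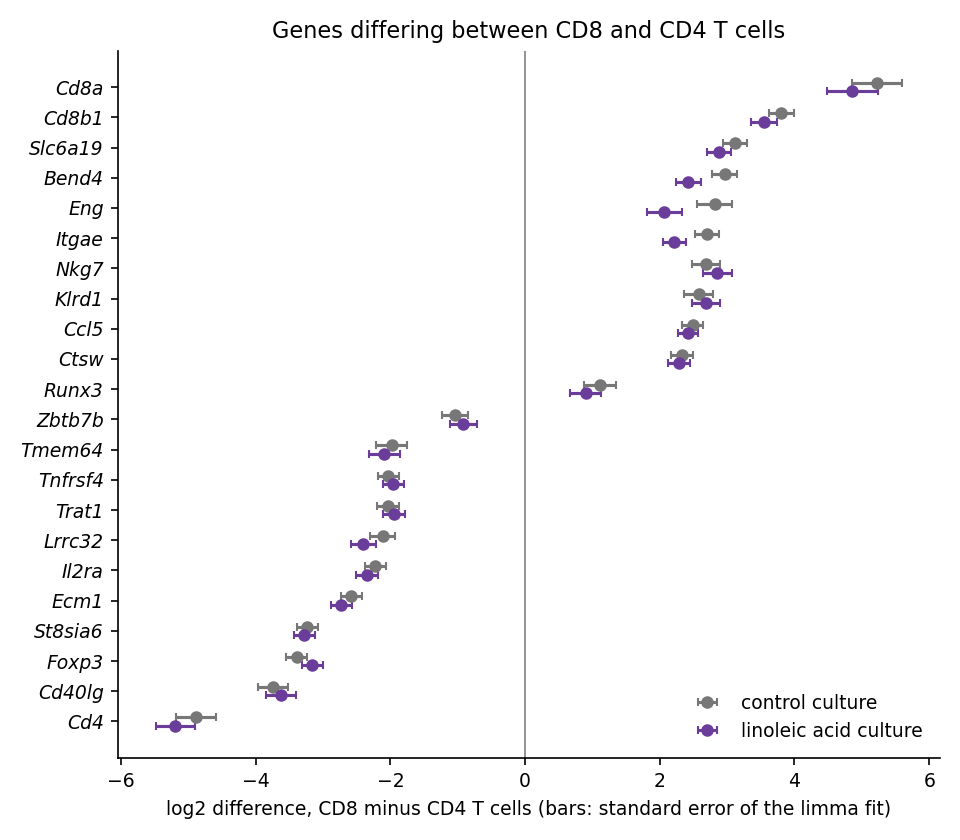
Log2 difference of CD8 minus CD4 T cells (horizontal axis) for the fixed lineage genes and the largest differences of the control culture, in control and in linoleic acid culture, with the standard error of the limma fit as bars. Cd8a stands at 5.23 and 4.86 and Cd4 at -4.88 and -5.19 in the respective cultures.

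In CD4 T cells, linoleic acid culture was compared with control culture. Cpt1a (probe set 17355915), the carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondrial oxidation, averaged log2 6.67 ± 0.30 (SD, n = 3) in control and 8.01 ± 0.31 in linoleic acid culture, 2.52-fold higher (log2 1.34 ± 0.23 SE), and same-numbered arrays differed by 1.34, 1.57 and 1.10. Nuclear-encoded electron transport chain genes lay lower with linoleic acid for 62 of 68 tested members, with a median of -0.20, and interferon-stimulated genes lay lower for 23 of 26, with a median of -0.17. Naive T cell and quiescence genes lay higher for 14 of 16, with a median of 0.14. The median over all 14323 genes was -0.00.

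Cpt1a was not past the threshold in limma without a block (adjusted p = 0.845) and passed with the replicate number as a block (adjusted p = 0.00335), within a range of 0.000462 to 1 over its 19 alternatives. An exact two-sided permutation test of its 6 arrays gave p = 0.1, the smallest that 3 against 3 can give. In limma 0 genes passed without a block, 1 passed with the block (Cpt1a), and 373 had an unadjusted p under 0.05 (804 with the block), 110 higher and 263 lower, where 716 were expected by chance. The arrays of the 2 cultures did not overlap for 7.44% of genes, against 10% by chance for independent arrays. Neither this share nor the 373 takes account of the paired numbers, so neither shows fewer differences than chance. Among genes with an unadjusted p under 0.05 and non-overlapping arrays, the largest other values above control were Thbs1 at 0.60, Mixl1 at 0.59, Plagl1 at 0.57 and Pla2g5 at 0.53, each in a gene below the 95th percentile of the receptor genes. The largest below control among these genes were Hmgn5 at -0.66 and Cfap97d2 at -0.61, also below that level, the ribosomal protein gene Rps20 at -0.63, the tubulin cofactor Tbca at -0.60 and the ATP synthase subunit Atp5mpl at -0.60.

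Among electron transport chain genes in CD4 T cells, 0 of 68 passed in limma over all genes and 0 adjusted over the list alone, with 13 at an unadjusted p under 0.05. With the block 4 were lower adjusted over the list alone. The NADH dehydrogenase subunits Ndufa12 and Ndufb8 stood at -0.44 and -0.48, the respiratory chain subunit Ndufa4 at -0.52 and the ATP synthase subunit Atp5g3 at -0.40, each with an unadjusted p under 0.05. Limma's camera gave the list an adjusted p = 2.64e-17, with adjusted p = 0.455 at an estimated correlation and 0.27 with fry, in a range of 3.3e-18 to 0.455 over 20 alternatives. The list means of the treated CD4 arrays ran from 7.28 to 7.41 and those of the control arrays from 7.43 to 7.57. Beside them the receptor genes averaged 3.18 ± 0.16 (SD, n = 3) in control and 3.23 ± 0.15 in linoleic acid culture.

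The interferon-stimulated genes in CD4 T cells included the antiviral effectors Ifit1 at -0.49, Ifit3 at -0.33 and Oasl1 at -0.28 and the nucleic acid sensor Zbp1 at -0.23, with 0 of 26 past the threshold in limma over all genes, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. Camera gave an adjusted p = 0.000756, and adjusted p = 0.963 with an estimated correlation, in a range of 6.15e-07 to 0.963. The naive and quiescence genes included the transcription factors Bach2 at 0.25, Satb1 at 0.22 and Foxp1 at 0.16 and the growth inhibitor Btg2 at 0.20, with 0 of 16 past either threshold and 0 at an unadjusted p under 0.05 in limma. Camera gave an adjusted p = 0.0207, and adjusted p = 0.963 with an estimated correlation, in a range of 0.000104 to 0.963. B cell markers averaged 7.80 ± 0.69 in CD4 control and 7.94 ± 0.77 in CD4 linoleic acid arrays, with 14 of 15 members higher and a median of 0.14. Camera gave them an adjusted p of 0.253 without a block and 0.000428 with it, in a range of 8.3e-07 to 0.993. With the block and an estimated correlation together the adjusted p = 0.532, and fry with the block gave 0.316. The direction of the B cell list turned without CD4 control replicate 1 (adjusted p = 0.19) or CD4 linoleic acid replicate 2 (0.993) or 3 (0.767), and the list passed without CD4 linoleic acid replicate 1 (8.3e-07) or CD4 control replicate 2 (0.00643) or 3 (0.0439). Without CD4 linoleic acid replicate 1 neither call held (interferon-stimulated genes, adjusted p = 0.515, and naive genes, 0.291), nor did the naive call without CD4 control replicate 2 (0.228) or replicate 3 (0.0902).

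The remaining lists did not pass in CD4 T cells, with camera adjusted p of 0.209 to 0.989. The 21 mitochondrial beta-oxidation genes had a median of 0.01, with 1 (Cpt1a) past the threshold adjusted over the list alone and Hadhb at -0.25, Eci2 at -0.23 and Echs1 at -0.20. PPAR target genes had a median of -0.00 and a mean of 0.11 (higher in camera), with Cpt1a again the 1 member past the threshold adjusted over the list alone. Medians were -0.02 for cholesterol synthesis, -0.00 for fatty acid synthesis (mean -0.00, and higher in camera), -0.02 for lipid uptake and storage, 0.01 for LXR targets, 0.01 for antioxidant and NRF2 targets and 0.04 for lipid peroxidation and ferroptosis genes. They were -0.05 for the integrated stress response, -0.03 for ER chaperones, 0.02 for apoptosis regulators (mean -0.01, and lower in camera), 0.01 for p53 targets, -0.06 for cell cycle genes and -0.02 for glycolysis and hypoxia genes (mean 0.00, and higher in camera). For T cell states they were 0.08 for activation, -0.10 for regulatory T cell, -0.04 for cytotoxic, -0.03 for CD4 lineage and -0.04 for CD8 lineage genes. Other blood cells had medians of 0.11 for myeloid, 0.05 for dendritic cell, 0.15 for NK cell and 0.02 for platelet markers.

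**Figure D2:**
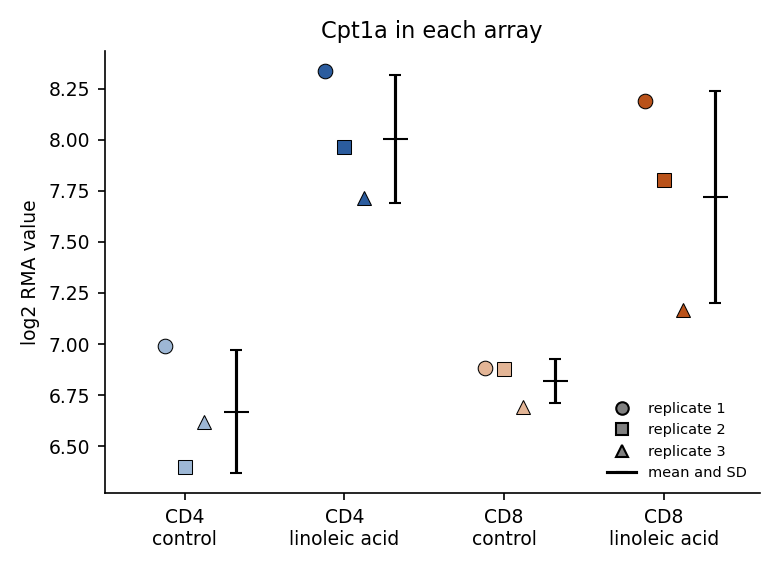
Log2 RMA value of Cpt1a (vertical axis) in each of the 12 arrays by group, with symbols for the replicate number and the group mean and SD beside them. The group means are 6.67 and 8.01 in CD4 T cells and 6.82 and 7.72 in CD8 T cells, in control and linoleic acid culture.

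In CD8 T cells the same treatment was compared with its control. Cpt1a averaged 6.82 ± 0.11 (SD, n = 3) in control and 7.72 ± 0.52 in linoleic acid culture, 1.87-fold higher (log2 0.90 ± 0.23 SE), and same-numbered arrays differed by 1.31, 0.93 and 0.47. PPAR target genes, the lipid-sensing programme to which Cpt1a belongs, lay higher for 10 of 13 tested members, with a median of 0.14. Interferon-stimulated genes lay lower for 24 of 26 (median -0.23), electron transport chain genes for 58 of 68 (-0.14) and cholesterol synthesis genes for 17 of 19 (-0.15), where the median of all genes was -0.06. Myeloid markers lay higher for 15 of 16 (0.12).

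Cpt1a in CD8 T cells had a limma adjusted p of 0.757 without a block and 0.0507 with it, in a range of 0.0133 to 1 over its 19 alternatives, and an exact two-sided permutation p of 0.1, the smallest possible. In limma 0 genes passed and 728 had an unadjusted p under 0.05 (1927 with the block), 338 higher and 390 lower, where 716 were expected by chance. With the block 1 gene passed, 1700091H14Rik, a predicted transcript named here after its values were seen, at 1.17 (adjusted p = 0.0194). Arrays of the 2 cultures did not overlap for 9.01% of genes, against 10% by chance for independent arrays. Neither this share nor the 728 takes account of the paired numbers. Among genes with an unadjusted p under 0.05 and non-overlapping arrays, the largest other values above control were Krtap5-2 at 1.17, Dcpp2 at 0.86, Cma2 at 0.71 and Lce3c at 0.70. The largest below it among these genes were Pnoc at -0.66, Zfp758 at -0.65, Borcs7 at -0.59, the antiviral Oasl2 at -0.57 and BC048403 at -0.56. Dcpp2, Cma2, Pnoc and Borcs7 lay below the 95th percentile of the receptor genes. The receptor genes averaged 3.17 ± 0.15 (SD, n = 3) in CD8 control and 3.34 ± 0.17 in CD8 linoleic acid arrays, and same-numbered arrays differed by 0.11, 0.25 and 0.13.

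Of the PPAR target genes in CD8 T cells, 1 (Cpt1a) passed adjusted over the list alone (2 with the block) and 0 over all genes in limma, with 3 at an unadjusted p under 0.05. The lipid droplet coat protein Plin2 stood at 0.39, the hormone gene Fgf21 at 0.37 and the pyruvate dehydrogenase kinase Pdk4 at 0.34, the last 2 below the 95th percentile of the receptor genes. Camera gave an adjusted p = 0.000895, adjusted p = 0.241 with an estimated correlation and fry 0.407, in a range of 2.54e-06 to 0.407. Of the interferon-stimulated genes 0 passed either threshold in limma and 7 had an unadjusted p under 0.05, and with the block 7 were lower adjusted over the list alone. The RNA sensor Ifih1 stood at -0.40, the antiviral Oas3 at -0.42, the regulator Irf7 at -0.34 and Cmpk2 at -0.45. Camera gave an adjusted p = 0.000396, and adjusted p = 0.698 with an estimated correlation, in a range of 4.8e-15 to 0.698. Without CD8 linoleic acid replicate 1 the interferon call ended (adjusted p = 0.288).

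The other 3 lists past camera's threshold in CD8 T cells were the myeloid, electron transport and cholesterol lists. Myeloid markers included the lysozyme Lyz2 at 0.52, the Fc receptor Fcgr3 at 0.48, the 1 member past the threshold adjusted over the list alone (2 with the block), and Cd68 at 0.26. Camera gave the myeloid list an adjusted p = 0.0034, and adjusted p = 0.843 with an estimated correlation, in a range of 9.74e-06 to 0.843. With the receptor gene level of each array as a covariate its direction turned (adjusted p = 0.00743). The electron transport subunits Ndufc1, Uqcrfs1 and Uqcrc1 stood at -0.37, -0.26 and -0.27, with 0 of 68 past either threshold in limma and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0152, and adjusted p = 0.843 with an estimated correlation). The cholesterol synthesis enzymes Pmvk, Dhcr7 and Msmo1 stood at -0.28, -0.35 and -0.26 and the regulator Srebf2 at -0.42, with 0 of 19 past either threshold in limma and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0334, and adjusted p = 0.843 with an estimated correlation). Among random lists matched on mean expression, a test chosen after the result was seen, the electron transport median lay at percentile 13.67 (matched median -0.11) and the cholesterol median at 16.19 (matched median -0.11). The PPAR median lay at 99.99 (matched median -0.07) and the myeloid median at 99.94 (-0.04). With the replicate block the electron transport and cholesterol calls ended, at adjusted p = 0.0531 (range 8.66e-05 to 0.843) and 0.0685 (range 0.00112 to 0.843). The myeloid call ended without CD8 control replicate 1 (0.276), CD8 linoleic acid replicate 2 (0.0827) or replicate 3 (0.649), and the electron transport call without CD8 linoleic acid replicate 1 (0.0967) or 2 (0.194) or CD8 control replicate 3 (0.379). The cholesterol call ended without CD8 control replicate 2 (0.205) or 3 (0.177) or CD8 linoleic acid replicate 1 (0.0706), 2 (0.103) or 3 (0.0676).

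**Figure D3:**
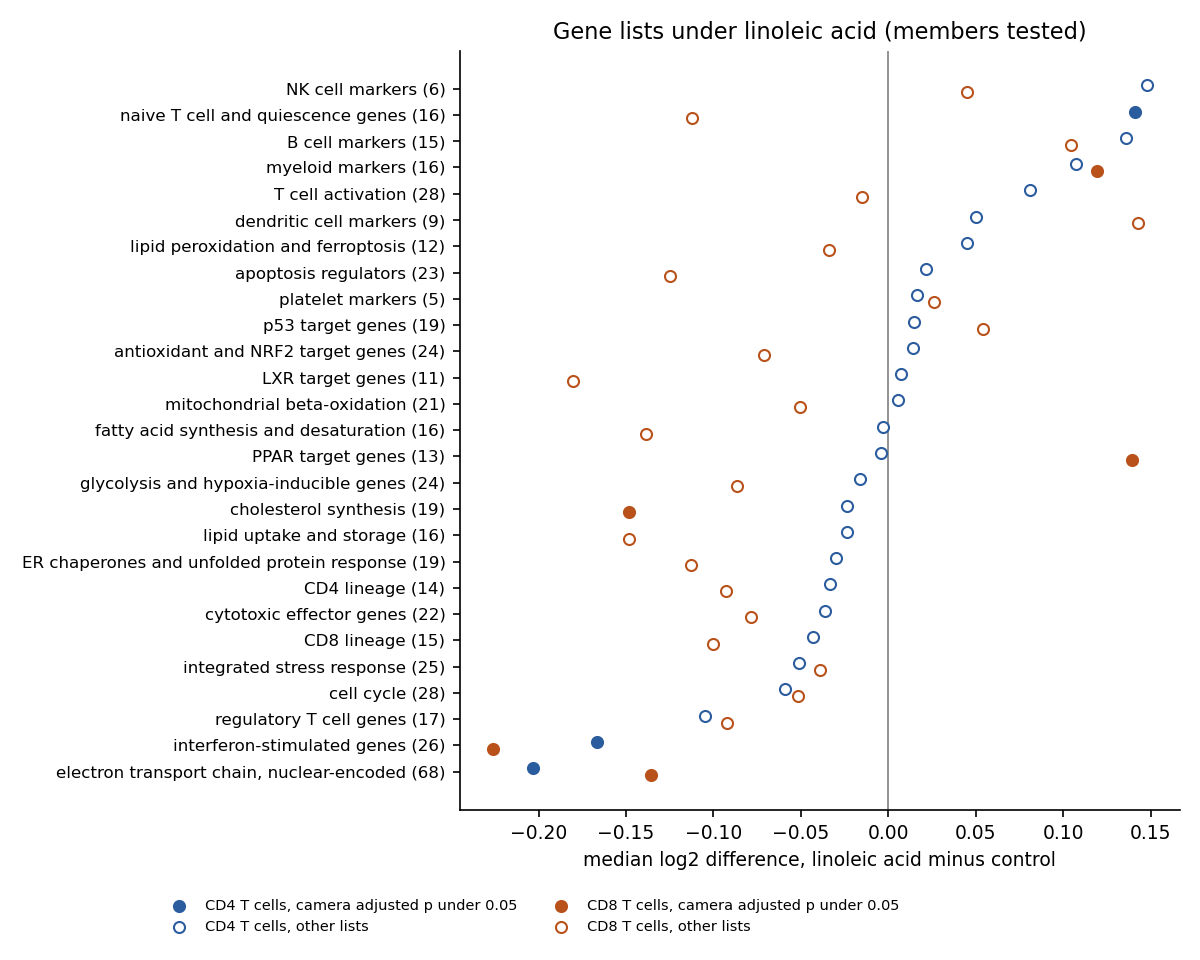
Median log2 difference of linoleic acid minus control (horizontal axis) over the tested members of each gene list, whose number stands in parentheses, in CD4 and CD8 T cells. Filled points mark an adjusted p under 0.05 in limma's camera at its preset correlation, and they lie between -0.23 for interferon-stimulated genes in CD8 T cells and 0.14 for PPAR target genes in CD8 and naive genes in CD4 T cells.

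The question of the series, a difference in response between the cell types, was tested as the effect in CD4 minus the effect in CD8 T cells. The Cpt1a effect was 0.43 ± 0.33 (SE, n = 3 per group) larger in CD4 T cells, with a 95% interval of -0.28 to 1.15 and a limma adjusted p of 0.953. It was 0.16 without CD8 linoleic acid replicate 3, 0.27 without CD4 linoleic acid replicate 1 and 0.67 without CD8 linoleic acid replicate 1. Electron transport chain genes differed with a median of -0.11, lower in CD4 T cells for 44 of 68, with Ndufa4 at -0.52 and the ATP synthase subunit Atp5g1 at -0.53. Naive and quiescence genes differed with a median of 0.23, to the CD4 side for 15 of 16, with the growth inhibitor Tob1 at 0.76, Bach2 at 0.46, Satb1 at 0.46 and Foxp1 at 0.25.

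In limma 0 of 14323 genes passed for this difference, with the block 0, and 336 had an unadjusted p under 0.05 (1189 with the block), 133 positive and 203 negative, where 716 were expected by chance. The 336 take no account of the paired numbers, so they do not show fewer differences than chance. The 5 smallest p belonged to Tmem25 at -0.77, the uracil glycosylase Ung at 0.65, Klrg2 at -0.72, the OX40 ligand Tnfsf4 at -0.97 and Osr1 at -0.67, of which Tmem25 and Tnfsf4 lay below the 95th percentile of the receptor genes. Camera gave the electron transport list an adjusted p = 0.00892, and adjusted p = 0.932 with an estimated correlation (range 1.03e-06 to 0.932). It gave the naive list an adjusted p = 0.00978, and adjusted p = 0.932 with an estimated correlation (range 0.00169 to 0.932). In each list 0 members passed in limma over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. Across genes, which are not independent replicates, the effects in the 2 cell types correlated at a Pearson r of 0.124 and a Spearman rho of 0.0218, and 57% of the 400 relabellings within cell types and 80% of the 20 relabellings of whole numbers gave a Pearson r of at least that size. The electron transport call ended without CD8 control replicate 1 (adjusted p = 0.0843) or CD8 linoleic acid replicate 1 (0.0798). The naive call ended without CD8 control replicate 1 (0.0843), CD4 linoleic acid replicate 1 (0.0635), CD4 control replicate 2 (0.0878) or CD8 linoleic acid replicate 3 (0.199). The correlation turned to -0.171 without CD4 control replicate 1 and to -0.137 without CD4 linoleic acid replicate 3.

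**Figure D4:**
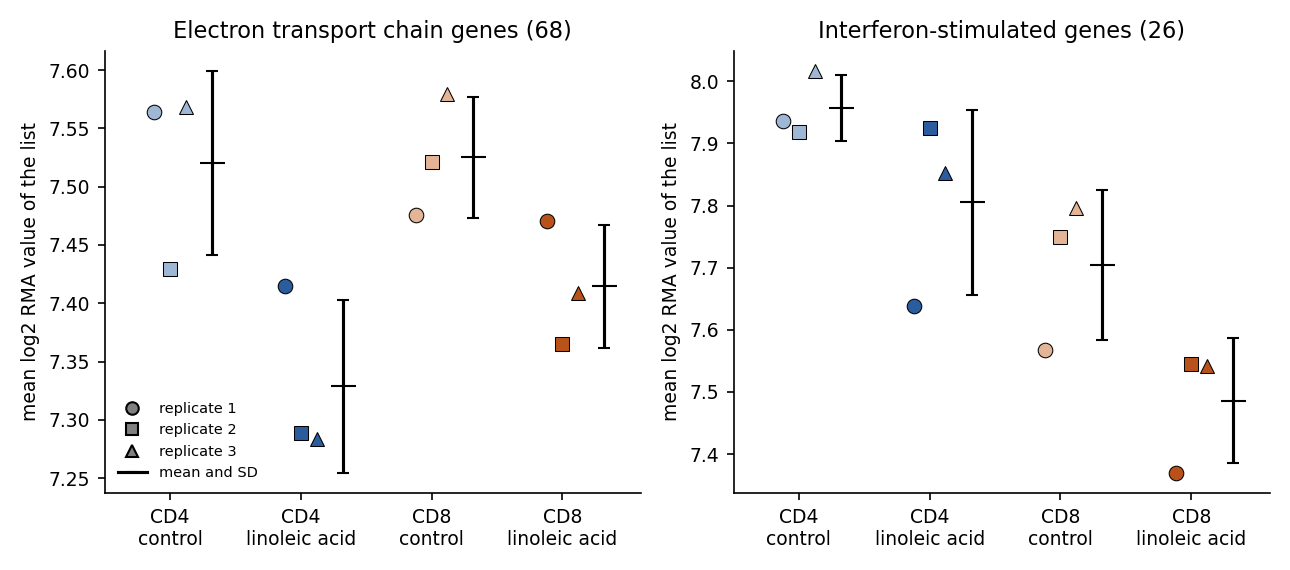
Mean log2 RMA value (vertical axes) of the electron transport chain genes and of the interferon-stimulated genes in each of the 12 arrays by group, with symbols for the replicate number and the group mean and SD beside them. The electron transport means of the treated CD4 arrays, 7.28 to 7.41, lie below those of the CD4 control arrays, 7.43 to 7.57.

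Linoleic acid culture gave the difference between the cell types under treatment. Cd8a was higher (log2 4.86 ± 0.38 SE, n = 3 per group, limma adjusted p = 3.92e-06) and Cd8b1 11.7-fold higher in CD8 T cells (3.55 ± 0.19, adjusted p = 1.83e-07), and Cd4 was 36.5-fold lower (-5.19 ± 0.29, adjusted p = 2.71e-07). Nkg7 at 2.85, Klrd1 at 2.68, Ly6c2 at 2.47, Ccl5 at 2.42, Ctsw at 2.28 and Itgae at 2.22 were higher in CD8 T cells, as were Slc6a19 at 2.88 and Bend4 at 2.42. Cd40lg at -3.62, St8sia6 at -3.28, Foxp3 at -3.16, Ecm1 at -2.73, Lrrc32 at -2.40, Il2ra at -2.35, the cytokine signalling inhibitor Socs2 at -2.23, Itih5 at -2.19 and Tmem64 at -2.09 were lower. Zbtb7b stood at -0.92 (adjusted p = 0.0269) and Runx3 at 0.90, with an adjusted p of 0.0829 without a block and 0.000485 with it (range 0.000377 to 0.261). Runx3 passed without CD8 linoleic acid replicate 3 (0.0203), and Zbtb7b no longer passed without CD4 linoleic acid replicate 1 (0.13) or 2 (0.085) or CD8 linoleic acid replicate 1 (0.0606) or 2 (0.122).

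In limma 291 genes passed in linoleic acid culture, 103 higher and 188 lower in CD8 T cells, 114 by more than 2-fold, and 798 passed with the block, 255 higher and 543 lower. Arrays of the cell types did not overlap for 15.3% of genes, against 10% by chance for independent arrays. Of the 280 genes of the control culture 194 passed in both cultures, all to the same side, and 278 had the same sign. The difference correlated across genes, which are not independent replicates, at 0.639 between the cultures. The CD8 lineage list had 10 of 15 higher, the CD4 lineage list 10 of 14 lower, the regulatory T cell list 13 of 17 lower and 1 higher, the cytotoxic list 7 of 22 higher and the activation list 7 of 28 lower (12, 12, 13 and 1, 9 and 8 adjusted over the list alone). Their adjusted p with an estimated correlation were 0.000465, 0.000465, 0.00246, 0.00384 and 0.0431, the highest over the 19 alternatives that change a single choice. With the block and an estimated correlation together they were 0.00989, 0.00989, 0.0153, 0.0153 and 0.056, which ends the activation call. The 291 genes became 179 without CD4 linoleic acid replicate 1, 150 without CD4 linoleic acid replicate 2 and 138 in a fit of only the 2 groups compared.

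Interferon-stimulated genes were lower in CD8 than in CD4 T cells in linoleic acid culture for 5 of 26 members (9 adjusted over the list alone), and for 8 with the block. These were Ifih1 at -0.90, Oasl2 at -1.02, the signal transducer Stat2 at -0.78, Ifit2 at -0.81 and Iigp1 at -0.86, the last chosen after its values were seen. Camera gave an adjusted p = 1.91e-06, and adjusted p = 0.248 with an estimated correlation (range 6.39e-11 to 0.248). Cholesterol synthesis genes had 1 of 19 lower, the sterol demethylase Cyp51 at -0.76, 5 with the block and 8 adjusted over the list alone (camera adjusted p = 0.000166, and adjusted p = 0.248 with an estimated correlation, range 3.54e-06 to 0.248). Naive and quiescence genes had 1 of 16 lower, Tob1 at -1.06, 3 with the block and 4 adjusted over the list alone (camera adjusted p = 0.00195, and adjusted p = 0.674 with an estimated correlation, range 0.000111 to 0.674). Electron transport chain genes lay higher in CD8 T cells for 51 of 68, with a median of 0.09, 0 past either threshold in limma and 4 at an unadjusted p under 0.05, and with the block 1 passed, Ndufa4 at 0.42. Camera gave this list an adjusted p = 0.000891, and adjusted p = 0.674 with an estimated correlation (range 1.65e-05 to 0.674). B cell markers lay lower for 15 of 15, with a median of -0.47, 0 past either threshold in limma and at an unadjusted p under 0.05 and 9 lower with the block. Their camera adjusted p was 0.0921 without a block and 1.16e-09 with it (range 3.86e-17 to 0.845), and 0.0344 with the block and an estimated correlation together.

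Several of these calls in linoleic acid culture ended when a single array was left out. The naive list no longer passed without CD8 linoleic acid replicate 3 (adjusted p = 0.0617), and Tob1 without CD4 linoleic acid replicate 1 (0.155) or 2 (0.111) or CD8 linoleic acid replicate 2 (0.112) or 3 (0.111). Cyp51 no longer passed without CD4 linoleic acid replicate 1 (0.0633) or 2 (0.0713) or CD8 linoleic acid replicate 2 (0.0606), and Oasl2 without CD8 linoleic acid replicate 1 (0.0613) or CD4 linoleic acid replicate 2 (0.138) or 3 (0.113). Stat2 no longer passed without CD4 linoleic acid replicate 2 (0.143) or 3 (0.0829) or CD8 linoleic acid replicate 3 (0.0723), and Ifit2 without CD4 linoleic acid replicate 1 (0.118) or 2 (0.0763) or CD8 linoleic acid replicate 2 (0.113) or 3 (0.0732). The B cell list passed without CD4 linoleic acid replicate 1 (1.8e-06) or CD8 linoleic acid replicate 2 (0.00537) or 3 (0.00182), and its direction turned without CD8 linoleic acid replicate 1 (0.611).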

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

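The tests of the array spread and of other cell types for Cpt1a, the relabelling of whole numbers, the matched lists for the difference between cell types and the receptor gene covariate were chosen only after the result they concern was seen.

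Electron transport chain genes stood out as a difference between the cell types, since the CD4 effect minus the CD8 effect had a median of -0.11 over 68 genes and a camera adjusted p of 0.00892. Naive T cell and quiescence genes did so with a median of 0.23 over 16 genes and a camera adjusted p of 0.00978. With an estimated correlation both had an adjusted p of 0.932. Among 10000 random lists matched on mean expression the first median lay at percentile 0 (matched median 0.11) and the second at 99.85 (matched median 0.07). Within the cell types the naive median lay at percentile 100 in CD4 (matched median 0.00) and at 13.44 in CD8 T cells (-0.07). Random lists lack the correlation between genes of a list, so these percentiles do not counter the 0.932.

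The first pattern weighed is the lower level of electron transport chain genes with linoleic acid in CD4 T cells, with an exact two-sided p of 0.1 for the list mean, the smallest possible, while the median in CD8 T cells lay at percentile 13.67 of matched random lists. A compressed range of the treated arrays is argued against by the list's median of -0.20 lying at percentile 0 among random lists matched on mean expression, whose median was -0.00. The spread between arrays stays open. The exact two-sided share of 0.005 of the 400 relabellings takes CD4 and CD8 arrays as independent. Same-numbered ones deviated together in linoleic acid culture (correlations of 0.58, 0.26 and 0.52), and in control culture they correlated at 0.54, -0.01 and 0.42. Whole numbers relabelled in both cell types gave 0.1, the smallest that 20 arrangements can give. A general fall of abundant short messages stays open, since 59 cytoplasmic ribosomal protein genes had a median of -0.0921 (95% interval -0.14 to -0.05), which is neither near 0 nor as low as the list. An effect of linoleic acid on these genes may remain beside both, as a hypothesis, with a fry adjusted p of 0.27 for the list, and 0.225 with the block.

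The second pattern is the higher level of Cpt1a in both cell types. The spread between arrays is argued against in CD4 T cells by the limma fit with the replicate block (adjusted p = 0.00335). Cpt1a also passed there with the random block, the block within each cell type, the covariate and both kinds of array weights. The estimation of the first kind of weights had not converged. Without the block limma gave 0.845 (range 0.000462 to 1), and the pairing was read from these same data. Same-numbered CD4 arrays differed by 1.34, 1.57 and 1.10. In CD8 T cells the spread stays open at adjusted p = 0.0507 with the block (0.757 without it, range 0.0133 to 1), where same-numbered arrays differed by 1.31, 0.93 and 0.47. Exact relabelling cannot decide in either cell type. It gave 0.1 within each cell type, 0.1 with whole numbers relabelled in both and 0.25 with cultures swapped within numbers, each the smallest possible. With array quality as measured by the receptor genes as a covariate, the change in CD4 T cells was 1.43 (SE 0.14), against 1.34 without it. This could hardly have come out otherwise, since the receptor level averaged 3.18 in CD4 control and 3.23 in CD4 linoleic acid arrays. In CD8 T cells the level averaged 3.17 and 3.34. The change there was 1.21 (SE 0.16) with the covariate, against 0.90 without it, which argues against array quality so measured in CD8 T cells. A larger share of cells of another type that escaped the sort is argued against in the arrays numbered 1. There Cpt1a rose by 1.34 in CD4 and 1.31 in CD8 T cells. B cell, myeloid, dendritic cell, NK cell and platelet list means changed by 0.04, 0.06, -0.07, 0.04 and 0.05 in CD4. In CD8 T cells they changed by 0.002, 0.06, -0.06, -0.07 and 0.06. Where myeloid markers rose by 0.31, in the CD8 arrays numbered 3, Cpt1a rose by 0.47. Over all arrays such cells stay open in both cell types. The highest upper interval end of the marker list medians was 0.37 in CD4 (6 NK cell markers, 3 of them also in another list) and 0.39 in CD8 T cells (5 platelet markers). But 14 of 15 B cell markers lay higher in CD4 T cells (camera adjusted p = 0.253, 0.000428 with the block and 0.532 with the block and an estimated correlation, range 8.3e-07 to 0.993). So did 15 of 16 myeloid markers in CD8 T cells (camera adjusted p = 0.0034, and adjusted p = 0.843 with an estimated correlation, range 9.74e-06 to 0.843), among them Lyz2 at 0.52 and Fcgr3 at 0.48 beside a Cpt1a change of 0.90. A response of Cpt1a in the T cells themselves is a hypothesis that these tests leave open beside the others.

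The third pattern is the lower level of interferon-stimulated genes with linoleic acid in CD8 T cells. A compressed range of the treated arrays is argued against only as the whole of the fall. The list's median of -0.23 lay at percentile 0.01 among matched random lists. Those lists themselves had a median of -0.11, so part of the fall may come from such a range. The random lists also lack the correlation between genes of this list, so the percentile is no p-value for it. The spread between arrays stays open on the same ground, with an exact two-sided share of 0.01 of the 400 relabellings and of 0.1, the smallest possible, with whole numbers relabelled, where the list mean stood at -0.15 in CD4 and -0.22 in CD8 T cells. Same-numbered arrays differed by -0.20, -0.20 and -0.25 in CD8 and by -0.30, 0.01 and -0.16 in CD4 T cells. A lower interferon response is a hypothesis, with an adjusted p of 0.698 at an estimated correlation and a fry adjusted p of 0.407, 0.0937 with the block, and a difference in interferon released by other splenocytes of the culture was not tested.

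Other splits of the same arrays were counted for each comparison. The 6 arrays of 2 groups make 10 splits, too few for a share under 0.05. With linoleic acid the real split gave 0 genes and the highest other 0 in CD4 T cells, and 0 and 0 in CD8 T cells, where a real count of 0 makes all 10 splits as large in advance and the count says nothing. Between the cell types the real split was the 1 that gave as many, with 280 genes against 1 at the highest other in control and 291 against 0 in linoleic acid culture. Among the 3 other splits that part as many pairs, in the fit with the replicate block, the highest count was 0 for linoleic acid in CD4 T cells (real 1), 0 in CD8 T cells (real 1) and 0 between the cell types in linoleic acid culture (real 798). The real split and these 3 are also too few for a share under 0.05, so these counts cannot decide on chance. For the difference between the effects the real count of 0 likewise fixed the outcome at 100 of 100 splits drawn, which says nothing about chance. The highest other of these splits gave 390, which points to a structure of the samples beyond the groups.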

How the results depend on the processing

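The block within each cell type, the receptor gene covariate, the gene-by-gene array weights and the mean over both cell types were chosen only after the result was seen. For genes changed in CD4 T cells the count of 0 was 1 with the replicate block, 1 with the random block, 1 with array weights, 1 with gene-by-gene weights, 1 with the block within each cell type, 1 with the covariate and 373 at an unadjusted p. For CD8 T cells it was 1 with the replicate block, 213 with array weights, 2 with the block within each cell type, 1 with the covariate and 728 at an unadjusted p, and for the difference between the effects 336 at an unadjusted p. Leaving out arrays gave 0 to 0 in these 3 comparisons. The 280 genes between cell types in control culture were 630 with the replicate block, 461 with the random block, 534 with the covariate, 1342 at an unadjusted p and 176 to 223 without 1 array, and each count except the last range held all 280. There same-numbered arrays correlated at 0.54, -0.01 and 0.42, so the numbers were not taken to pair them. The 291 in linoleic acid culture were 798 with the replicate block, 523 with the random block, 138 with only the groups compared, 2299 with array weights, 644 with gene-by-gene weights, 572 with the covariate, 1689 at an unadjusted p and 150 to 322 without 1 array. The estimation of the array weights stopped before converging (weights 0.286 to 4.91), and the cause of the other shifts was not tested.

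The Cpt1a change in CD4 T cells passed at 1.34 with the replicate block, 1.34 with the random block, 1.34 with array weights, 1.35 with gene-by-gene weights, 1.34 with the block within each cell type and 1.43 with the covariate (adjusted p 0.000462 to 0.0463), and was 1.17 to 1.498 without 1 array. In CD8 T cells it passed at 0.98 with array weights and 1.21 with the covariate (adjusted p 0.0347 and 0.0133) and was 0.67 to 1.18 without 1 array. The difference was 0.16 to 0.67 without 1 array. Lists past the threshold in CD4 T cells numbered 3, and 7 with the block within each cell type, 5 with the covariate, 0 with an estimated correlation, 0 with fry and 3 to 6 without 1 array. In CD8 T cells the 5 were 8 with no filter, 3 with the replicate block, 3 with quantile normalization, 3 with the block within each cell type, 14 with the covariate, 0 with an estimated correlation, 0 with fry and 2 to 7 without 1 array. For the difference the 2 were 1 with no filter, 0 with array weights, 5 with the covariate, 0 with an estimated correlation, 0 with fry and 0 to 3 without 1 array. Between cell types the 8 in control culture were 5 with an estimated correlation (7 to 10 without 1 array), and the 9 in linoleic acid culture were 5 (9 to 12). The direction turned for myeloid markers in CD8 T cells with the covariate (adjusted p 0.00743) and for B cell markers in CD4 T cells with the covariate (0.59) and without CD4 control replicate 1 (0.19) or CD4 linoleic acid replicate 2 (0.993) or 3 (0.767), where the other arrays left out kept it (from 8.3e-07). It also turned for B cell markers between cell types without CD8 control replicate 1 (0.815) and without CD8 linoleic acid replicate 1 (0.611), and was kept without each other array (3.87e-05 at the lowest in control, and 1.8e-06 to 0.736 in linoleic acid culture). The correlation of the effects, 0.124, turned without CD4 control replicate 1 (-0.171) or CD4 linoleic acid replicate 3 (-0.137) and was at most 0.289 without another array.

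Over all alternatives, those above included, 3584 of 3789 alternatives of 205 named gene results kept direction and side of the threshold, 62 lost and 143 gained a call and 0 turned, and 500 of 609 alternatives of 31 list results kept both. With linoleic acid in either cell type and for the difference between the effects, the replicate block changed no call over all genes, and no list call at the preset correlation, besides those given beside the results. Between the cell types in linoleic acid culture it added genes of further lists, among them Msmo1, Bcl2, Satb1 and Bach2, and no list call besides that given. In control culture it ended the call of the cholesterol list (0.0643) and passed the B cell list (1.1e-09, and adjusted p = 0.0342 with an estimated correlation as well) and the myeloid list (0.0253, and adjusted p = 0.391 with an estimated correlation as well). With both choices the activation list there had an adjusted p = 0.062, which ends its call. The correlation of the effects over called genes gave no value, with 0 genes called, and the random block was not run for lists. The mean effect over both cell types gave 0 genes, and 26 with the block. Signal over background limits 4495 of 14323 genes, which lay below the 95th percentile of the receptor genes.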

Other observations

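The mean over both cell types, the levels of single marker genes and the correlation of the effects over relabellings were tests chosen only after the result was seen.

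Averaged over both cell types, with 6 arrays on each side, Cpt1a was 1.12 higher with linoleic acid (limma adjusted p = 0.147 without a block and 0.000348 with it). Same-numbered CD4 and CD8 arrays deviated together in linoleic acid culture, so the 6 arrays of a side may not be independent. Exact relabelling of whole numbers gave 0.1 for Cpt1a and cultures swapped within numbers 0.25, each the smallest possible. Without a block 0 genes passed in limma and 693 had an unadjusted p under 0.05. With the block 26 passed, 23 higher and 3 lower, and 1396 had an unadjusted p under 0.05. Of the 26 genes that passed, 9 were chemosensory receptor genes, all higher, where such genes made up 245 of the 14323 tested. Another 9 of the 26 were predicted or small RNA genes. The ribosomal protein gene Rps20 fell by 0.51 (adjusted p = 0.03). In the fit with the block, fry gave electron transport chain genes, interferon-stimulated genes and PPAR target genes an adjusted p of 0.0411 each, where the estimated correlation gave 0.309, 0.205 and 0.187. Markers of other cells lay higher in the same fit, with a camera adjusted p of 1.13e-05 for myeloid and 4.47e-05 for B cell markers, and adjusted p = 0.205 for each with an estimated correlation.

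The activation gene Nr4a1, an early response gene of T cell receptor signalling, stood at 0.71 in CD4 and 0.64 in CD8 T cells with linoleic acid, neither past the threshold in limma (adjusted p = 1 and 0.757). In CD8 T cells the platelet markers Itga2b at 0.34 and Treml1 at 0.39 passed adjusted over the list alone, and the list itself did not (camera adjusted p = 0.218). The T-box factor Eomes of memory CD8 T cells stood at -0.54, Fosb at -0.69 and the sterol exporter Abcg1 at -0.49, none past the threshold.

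The arrays numbered 1 differed from the others in markers of cells that the sort is meant to remove. Cd8a averaged 5.21 in the CD4 arrays numbered 1 and 6.47 and 6.63 in those numbered 2 and 3, and Cd4 averaged 5.22 in the CD8 arrays numbered 1 and 6.32 and 6.17 in the others. The B cell gene Cd79a averaged 8.86, 10.5 and 10.4 in CD4 arrays and 8.14, 9.96 and 10.1 in CD8 arrays numbered 1, 2 and 3. Each of these averages lay above 5.11, the 95th percentile of the receptor genes, so B cell signal remained after the sort under every number. Of 8413 unnamed probe sets past the filter, 13 differed between the cell types in each culture and 0 with linoleic acid in limma, with 293 at an unadjusted p under 0.05 in CD4 and 409 in CD8 T cells.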
